A study of Mus musculus with 15 samples.

How the data were processed

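MPI cells, self-renewing mouse macrophages grown in GM-CSF that derive from fetal liver of the C57BL6/J strain, were sampled 24 h after exposure to elongated mineral particles or without exposure. Per the labels' protocols, RNA was purified from lysed cells, mRNA was enriched with oligo(dT) beads, and libraries were made with dUTP second-strand synthesis. Selection by oligo(dT) can change the yield of transcripts with short poly(A) tails, among them those of mitochondria. Per the submitters' processing notes, cutadapt, HISAT2 and StringTie were used with the GRCm38 build. Their versions, settings, roles and the annotation release are not given in the sources used here. The authors deposited a table of 10653 genes and a table of 22795 transcripts with 15 libraries each, and FPKM is the unit that the deposited values point to. All entries are protein-coding, and the highest group mean of each is at least 0.5003 FPKM for genes and 0.5001 FPKM for transcripts, so genes below about 0.5 FPKM in every group could not be examined. Deposited FPKM were used as given. FPKM are relative to the other transcripts of a library, so a change in abundant transcripts moves the rest.

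Gene symbols, identifiers and positions are those of the deposited tables. Of the gene identifiers, 87.21% were found with the same version in the GENCODE M21 annotation and 99.82% without the version, and 100% of these lay at the same position. There were 9 symbols on more than 1 line, kept apart by identifier. For 828 genes with 1 transcript, 100% of values were equal in both tables within a relative tolerance of 0.001. No counts or whole reads could be recovered, so no test on counts was run, the depth is unknown and no interval for counting error could be given. Of the tested genes 10549 had no library at 0. A value of 0 can be a failed estimate, and such genes are described as listed at 0. Reads shared between near-identical genes, as in the Ear, Ifi200, Ifit and Gbp families, can be split uncertainly, so values of their members are uncertain.

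Groups were taken from the labels. The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes at 0.5 FPKM or more in at least 3 libraries (10616) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) in 1 fit of all 15 libraries by group, and p-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. Each treatment was compared with untreated cells, asbestos with fragments within each mineral, and the minerals within each habit. The difference of the asbestos effects between minerals and their mean over both minerals were tested in the same fit. Of 36 gene lists, 31 with at least 3 measured members were tested with camera of limma at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, and adjusted within each comparison. Member counts are given over all genes tested, and adjusted over the list alone where these counts differ.

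Named genes are, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold whose libraries did not overlap, with a mean of at least 1 FPKM in the higher group and no predicted or clone symbol, together with up to 4 members of each list with the smallest p. A further 15 genes of inflammation and stress were named whatever their p, of which Il6, Ptgs2 and Nqo1 were not among the genes tested. Some genes that the rule takes are not reported here. Overlaps between treatments were set beside 100 simulations of unchanged groups with shared controls. The share of mitochondrial genes was compared by an exact 2-sided permutation test.

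Alternatives were TMM rescaling and quantile normalization, a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, the replicate number as a block, only the groups compared in the fit, no mean-variance trend, an absolute log2 fold change of at least 1, sums of transcripts and the omission of each library. Chosen after the data were seen were the omission of both riebeckite libraries with the same number and rescaling to nuclear genes. The code was tested on simulated data from 10616 genes with 200 changed in each of 5 draws. For riebeckite asbestos against untreated cells it recovered 62.4, 91.4 and 97.9% of genes changed by 1.25, 1.5 and 2 times (5.94% of calls false). Against fragments it recovered 58.9, 91.2 and 97.0% (3.94% false), and for the difference between minerals 32.7, 76.6 and 90.6% (5.36% false). A list moved on purpose was called, and 0 of 29 others, which does not rate correlated real lists. Plots used matplotlib 3.10.9 in Python 3.11.15.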

Results

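RNA was profiled in MPI cells, non-transformed mouse macrophages named after the Max Planck Institute that self-renew in culture with the growth factor GM-CSF and serve as a model of alveolar macrophages. The cells were left untreated or exposed for 24 h to elongated particles of a pair of amphibole minerals, each in an asbestiform habit of thin fibres and as non-asbestiform cleavage fragments. Doses were matched by surface area, at 9 µg/cm² of riebeckite asbestos, 40 µg/cm² of riebeckite cleavage fragments, 5 µg/cm² of tremolite asbestos and 60 µg/cm² of tremolite cleavage fragments, so mass differed between treatments. Each of the 5 groups held 3 libraries, 15 in all, and gene levels were given as FPKM for 10653 protein-coding genes. Summed FPKM lay between 257329 and 273570 per library, and the read depth behind these values is unknown. Spearman's rho across genes was 0.988 to 0.992 within groups and 0.964 to 0.990 between groups, and 0 pairs of libraries held identical values. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Unless stated otherwise, levels are mean FPKM ± SD with n = 3 per group, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM.

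The first question was how far each particle changed gene expression at 24 h. Of 10616 genes tested, 2232 were higher and 2575 lower after riebeckite asbestos than in untreated cells, 1626 and 2447 after riebeckite fragments, 1062 and 1478 after tremolite asbestos, and 1328 and 1592 after tremolite fragments (limma, adjusted p under 0.05). Most changes were small, with median absolute log2 fold changes among the called genes of 0.30, 0.29, 0.27 and 0.28 in that order, and 256, 189, 67 and 92 genes changed by at least 1 on the log2 scale. Levels in the 3 treated and 3 untreated libraries did not overlap for 55.3, 49.1, 39.9 and 45.1% of genes, where chance gives 10%. Across all 5 groups 5060 genes differed. The share of higher among called genes moved with the scaling of the libraries. For riebeckite fragments it was 39.9% as deposited and 50.6% after TMM rescaling, for tremolite asbestos 41.8% and 54.8%, and for tremolite fragments 45.5% and 52.7%, so the balance turned with TMM rescaling. After quantile normalization these 3 shares were 44.1, 45.6 and 46.9%, and the balance did not turn. Rescaling to the nuclear genes, chosen after the data were seen, gave 28.6, 35.0 and 42.1%, and for riebeckite asbestos 36.0% in place of 46.4%.

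**Figure D1:**
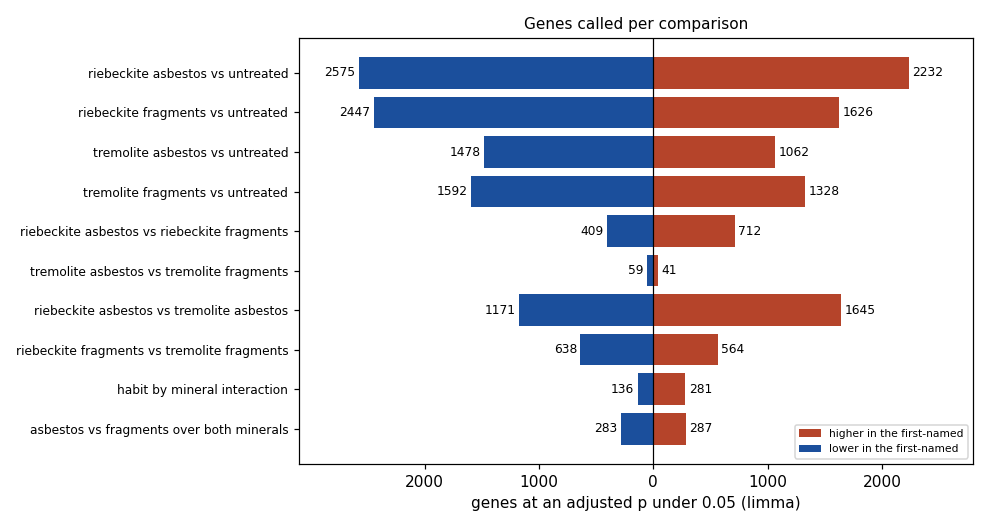
Genes at an adjusted p under 0.05 (limma) in 10 comparisons, with bars to the right for genes higher and to the left for genes lower in the first-named group. Riebeckite asbestos against untreated cells had the longest bars, 2232 higher and 2575 lower, and the tremolite pair the shortest, 41 and 59.

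Riebeckite asbestos raised H2-M2, a non-classical MHC class I gene (ENSMUSG00000016283.13, chromosome 17, 37480851 to 37483552, GRCm38), from 0.756 ± 0.0483 to 47.4 ± 3.62 FPKM, a log2 fold change of 4.78 (SE 0.0797, limma adjusted p = 6.18e-13). Acod1, which makes itaconate in activated macrophages (ENSMUSG00000022126.6, chromosome 14, 103046977 to 103056573), rose from 0.710 ± 0.0690 to 20.1 ± 2.58 FPKM (3.62, SE 0.0713), and Inhba, the activin A subunit (ENSMUSG00000041324.14, chromosome 13, 16011851 to 16031621), from 2.03 ± 0.252 to 32.6 ± 0.760 (3.48, SE 0.0840). Cfb, the complement factor B gene, reached 123 ± 13.8 FPKM against 10.8 ± 0.943 (3.40). Other large rises were those of Acp5 (3.19), Hp (2.85), Slc6a12 (2.78), Krt79 (2.64) and Pdpn (2.54), and large falls those of Adgre4 (-2.33), Clec4a3 (-2.25), Ms4a8a (-2.13), Elovl6 (-1.90) and Clec12a (-1.77). Ifitm6 was listed at 0 in all 3 asbestos libraries and at 3.80, 3.85 and 3.03 FPKM in untreated cells.

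Among inflammatory cytokines and chemokines, 12 of 16 measured members rose and 2 fell after riebeckite asbestos, and of the NF-kB feedback genes 15 of 17 rose and 0 fell, with the same counts adjusted over each list alone. Il1b went from 10.9 ± 1.38 to 42.2 ± 3.81 FPKM (1.87, SE 0.0874, limma adjusted p = 2.14e-09), Tnf from 7.21 ± 0.884 to 17.5 ± 2.40 (1.17) and Cxcl2 from 1.65 ± 0.229 to 4.23 ± 1.27 (0.95), whereas Ccl2 was not called (0.21, limma adjusted p = 0.502). Nfkb2 (0.80), Sod2 (0.73) and Nfkbie (1.02) rose as well. List medians were 0.55 and 0.69 (camera adjusted p = 0.000322 and 1.12e-07), and with an estimated correlation the adjusted p = 0.111 and 0.0983. Of 23 Nrf2 oxidative stress genes 13 rose and 3 fell, led by Hmox1, which degrades heme (84.9 ± 3.35 to 203 ± 8.81 FPKM, 1.25), and Srxn1 (1.05). The cystine importer gene Slc7a11, a member of both the Nrf2 and the amino acid response list, rose by 0.79. The median of the Nrf2 list was 0.41 (camera adjusted p = 0.000322, and adjusted p = 0.193 with an estimated correlation). The stress cytokine Gdf15 rose by 1.08.

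Lipid and lysosome genes rose after riebeckite asbestos in 12 of 16 members of the LXR and lipid efflux list, 12 of 24 of the cholesterol synthesis list and 21 of 33 of the lysosome list, while 3, 3 and 5 fell. Adjusted over the list alone, 12, 14 and 22 rose. The efflux transporter Abca1 rose by 1.44, Acat2 by 0.60 and the protease gene Ctsk by 1.16, and the fatty acid carrier Fabp4 fell by 1.49. Camera gave adjusted p = 0.000867, 0.0136 and 3.60e-05. An estimated correlation gave adjusted p = 0.0983, 0.193 and 0.224. Matrix remodelling genes (10 of 16 rose, 3 fell) and growth factors and fibrosis mediators (6 of 11 rose, 2 fell) included Tgm2 (1.90) and Spp1, osteopontin (1.84). They had camera adjusted p = 0.00221 and 0.00606. These became adjusted p = 0.181 and 0.0983 with an estimated correlation. Alveolar macrophage markers rose in 19 of 29 cases and fell in 7 (camera adjusted p = 1.84e-05, and adjusted p = 0.0983 with an estimated correlation). Glycolysis genes rose in 13 of 23 cases, among them Hk2 (0.77) and Pgam1 (0.62), and fell in 2 (camera adjusted p = 0.00394, and adjusted p = 0.353 with an estimated correlation). Higher and lower counts adjusted over the list alone were 10 and 4 for matrix genes, 20 and 7 for alveolar markers and 13 and 3 for glycolysis.

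Genes of DNA replication fell in 17 of 35 cases after riebeckite asbestos and rose in 0, with Mcm6 lower by 0.41 and Rrm2 by 0.37, and ribosomal protein genes fell in 19 of 36 and rose in 0 (18 and 24 lower adjusted over the list alone). Tested with camera, they had adjusted p = 0.000867 and 0.000336. The same lists had adjusted p = 0.275 and 0.523 with an estimated correlation. All 13 transcripts of the mitochondrial genome fell, with a median of -0.44 (camera adjusted p = 1.81e-05, and adjusted p = 0.275 with an estimated correlation). Their share of summed FPKM was 6.44 ± 0.419% after riebeckite asbestos and 8.65 ± 0.181% in untreated cells, without overlap between the libraries (exact 2-sided permutation p = 0.1, the smallest that 3 against 3 allows). With the other treatments the share was 7.91 ± 0.395% (riebeckite fragments), 8.16 ± 0.172% (tremolite asbestos) and 8.42 ± 0.281% (tremolite fragments), with exact p = 0.1, 0.1 and 0.5 against untreated cells.

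The remaining lists were not called for riebeckite asbestos, although single members changed. Inflammasome genes were 2 higher and 7 lower of 14 (camera adjusted p = 0.126), with Il18 lower by 1.28 and Casp1 by 0.46, and metallothioneins 4 higher and 1 lower of 7 (camera adjusted p = 0.152), with Mt2 higher by 0.84. Iron handling genes were 8 higher and 4 lower of 13 (camera adjusted p = 0.204), with the iron exporter Slc40a1 lower by 0.87, scavenger receptors 10 higher and 7 lower of 21 (camera adjusted p = 0.355), with the oxidised LDL receptor Olr1 higher by 1.39 and the mannose receptor Mrc1 lower by 0.80, and G2/M genes 3 higher and 15 lower of 30 (camera adjusted p = 0.126). The p53 targets were 9 higher and 6 lower of 22 (camera adjusted p = 0.381), amino acid response genes 8 higher and 2 lower of 20 (camera adjusted p = 0.33), nuclear respiratory chain genes 7 higher and 3 lower of 32 (camera adjusted p = 0.309), immediate early genes 4 higher and 7 lower of 16 (camera adjusted p = 0.567), alternative activation genes 3 higher and 3 lower of 8 (camera adjusted p = 0.517) and histone genes 2 higher and 0 lower of 7 (camera adjusted p = 0.204). Interferon genes were 1 higher and 3 lower of 26 (camera adjusted p = 0.878), unfolded protein response genes 2 higher and 3 lower of 18 (camera adjusted p = 0.708), heat shock genes 2 higher and 2 lower of 14 (camera adjusted p = 0.985) and dendritic cell markers 2 higher and 2 lower of 7 (camera adjusted p = 0.873). In these last 4 lists the median and the mean differed in sign, at 0.0046 and -0.13, 0.015 and -0.025, -0.028 and 0.013, and 0.086 and -0.039. For every list called in any of the 10 comparisons the median, the mean and the camera test had the same sign. Markers of other macrophages were 2 higher and 4 lower of 7 (camera adjusted p = 0.446), of neutrophils 2 higher and 0 lower of 3 (camera adjusted p = 0.0715) and of fibroblasts, epithelium and endothelium 1 higher and 1 lower of 3 (camera adjusted p = 0.613). The other 5 lists, for mast cells, erythroid cells, progenitors, hepatocytes and lymphocytes, had 1, 1, 2, 2 and 1 measured members and were not tested. The higher and lower members adjusted over the list alone numbered 3 and 16 for mitosis, 10 and 7 for p53 targets, 2 and 1 for respiratory chain and 1 and 2 for interferon.

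Riebeckite cleavage fragments raised H2-M2 to 17.6 ± 1.29 FPKM (3.41, SE 0.0797, limma adjusted p = 2.26e-11), Acp5, the tartrate-resistant acid phosphatase gene, from 2.99 ± 0.239 to 28.9 ± 1.30 (2.91) and Inhba to 17.5 ± 0.592 (2.61). Cxcr2, a chemokine receptor, rose from 2.51 ± 0.0906 to 19.0 ± 2.25 FPKM (2.51, SE 0.103, limma adjusted p = 1.00e-09) and Siglecf, a lectin typical of alveolar macrophages, from 10.7 ± 1.05 to 55.4 ± 2.97 (2.27). Ch25h, which makes 25-hydroxycholesterol, fell by 1.91 and Emilin2 by 1.87, while Ifitm6 was listed at 0.111, 0 and 0.124 FPKM. Il1b rose to 25.2 ± 0.694 FPKM (1.15), and Tnf, at 8.89 ± 1.45 FPKM, was not called (0.26, limma adjusted p = 0.0981). It was called without fragment library 3 (0.38, limma adjusted p = 0.0249). Hmox1 rose to 182 ± 7.42 FPKM (1.09).

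The lists of alveolar macrophage markers (22 of 29 rose, 5 fell), matrix remodelling (11 of 16 rose, 2 fell), LXR and lipid efflux (12 of 16 rose, 2 fell) and neutrophil markers (3 of 3 rose) were called after riebeckite fragments with camera adjusted p = 1.10e-10, 5.79e-06, 3.77e-06 and 0.000781, and held with an estimated correlation (adjusted p = 0.0184, 0.0438, 0.0184 and 0.0387). Over the list alone, 23, 11, 13 and 3 rose. Examples were Spp1 (2.08), Tgm2 (1.38) and Mmp2 (1.35) for matrix and Abca1 (1.15) and Cd36 (0.97) for lipid efflux. Of 18 neutrophil markers only Cxcr2, S100a8 (0.87) and the collagenase gene Mmp8 (0.77) were measured. Nrf2 genes rose in 17 of 23 cases and fell in 1, lysosome genes rose in 21 of 33 and fell in 2, cytokines rose in 9 of 16 and fell in 4, and NF-kB genes rose in 10 of 17 and fell in 0. These had camera adjusted p = 1.02e-06, 3.48e-07, 0.00938 and 0.000672. Estimating the correlation gave adjusted p = 0.0736, 0.144, 0.177 and 0.192 instead. Cholesterol synthesis (9 of 24 rose, 3 fell) and growth factor genes (5 of 11 rose, 2 fell) had camera adjusted p = 0.0106 and 0.00657. With the correlation estimated, adjusted p = 0.146 and 0.0535 resulted. DNA replication genes fell in 22 of 35 cases and rose in 0 (median -0.24, camera adjusted p = 4.47e-06, and adjusted p = 0.144 with an estimated correlation). With p adjusted over the list alone, higher and lower counts were 22 and 3 for lysosome, 10 and 3 for cholesterol synthesis and 0 and 25 for DNA replication. The cytokine call ended among genes with a mean of at least 5 FPKM (camera adjusted p = 0.09). The early response genes Klf2 and Myc fell by 1.76 and 0.97.

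For p53 targets, 8 of 22 rose, Phlda3 by 0.93, and 2 fell after riebeckite fragments (camera adjusted p = 0.0348, and adjusted p = 0.225 with an estimated correlation), and 9 of 36 ribosomal protein genes fell and 0 rose (camera adjusted p = 0.0456, and adjusted p = 0.801 with an estimated correlation). Higher and lower counts adjusted over the list alone were 9 and 3 for p53 targets and 0 and 7 for ribosomal proteins. The p53 call ended without untreated library 1 (camera adjusted p = 0.0691) or fragment library 3 (0.0522). The ribosomal call ended without untreated library 1 (0.233) or fragment libraries 2 or 3 (0.0804 and 0.267), after TMM rescaling (0.131) and among genes with a mean of at least 5 FPKM (0.0543).

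Tremolite asbestos raised H2-M2 to 26.6 ± 2.94 FPKM (3.97, SE 0.0797, limma adjusted p = 6.53e-12), Cfb to 69.1 ± 5.64 (2.58), Acod1 to 8.69 ± 0.206 (2.50) and Inhba to 15.2 ± 2.11 (2.42). Tnfrsf9, the costimulatory receptor CD137, rose from 0.188 ± 0.0205 to 3.52 ± 0.741 FPKM (1.91) and Il7r from 0.698 ± 0.0857 to 5.02 ± 0.335 (1.83). Tnf rose by 1.08 (SE 0.119), Il1b reached 25.4 ± 1.63 (1.16) and Cxcl2 4.50 ± 0.263 FPKM (1.05). Clec4a3 fell by 1.10 and Gda, guanine deaminase, from 109.9 ± 0.989 to 51.5 ± 0.324, by 1.08. Hmox1 rose by 0.63.

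Cytokines (9 of 16 rose, 1 fell), NF-kB genes (12 of 17 rose, 0 fell), matrix genes (8 of 16 rose, 1 fell), growth factors (6 of 11 rose, 1 fell) and alveolar macrophage markers (20 of 29 rose, 5 fell) were called after tremolite asbestos, with camera adjusted p = 1.00e-06, 2.14e-10, 5.66e-06, 0.00017 and 9.87e-11. All 5 held with an estimated correlation (adjusted p = 0.0319, 0.0326, 0.0326, 0.0259 and 0.0222), and 9, 13, 9, 6 and 20 members rose adjusted over the list alone. Examples were Il1a (0.74), Nfkbie (0.73), Spp1 (1.34), Tgm2 (1.18), Tgfbi (1.46) and Csf2rb (0.91). DNA replication genes fell in 27 of 35 cases and rose in 0 (28 lower adjusted over the list alone), with Mcm6 (-0.51), Rrm2 (-0.59) and Uhrf1 (-0.49), a median of -0.34 and camera adjusted p = 3.57e-13, which also held (adjusted p = 0.0319 with an estimated correlation). In the interferon list 6 of 26 genes rose, 0 fell and 20 were not called, or 11 higher adjusted over the list alone, with Bst2 higher by 0.89 and Irf9 by 0.67. The interferon median of 0.74 had a camera adjusted p = 1.48e-06. An estimated correlation gave adjusted p = 0.4. Lysosome (15 of 33 rose, 1 fell), glycolysis (11 of 23 rose, 1 fell), LXR (9 of 16 rose, 3 fell), p53 (6 of 22 rose, 1 fell) and ribosomal protein genes (0 of 36 rose, 15 fell) had camera adjusted p = 4.37e-07, 0.000268, 0.00335, 0.0127 and 4.94e-05. These became adjusted p = 0.132, 0.234, 0.0722, 0.194 and 0.453 with an estimated correlation. The higher and lower members adjusted over the list alone numbered 6 and 2 for growth factors, 20 and 7 for alveolar markers, 18 and 2 for lysosome, 10 and 4 for LXR, 7 and 1 for p53 targets and 0 and 20 for ribosomal proteins.

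Nrf2 genes rose in 9 of 23 cases and fell in 3, scavenger receptors rose in 8 of 21 and fell in 4, and cholesterol synthesis genes fell in 7 of 24 and rose in 0 after tremolite asbestos, with camera adjusted p = 0.0149, 0.0241 and 0.0495. The same lists had adjusted p = 0.292, 0.0741 and 0.239 with an estimated correlation. With p adjusted over the list alone, higher and lower counts were 11 and 4 for Nrf2 genes and 9 and 4 for scavenger receptors. Idi1 fell by 0.34 and Stard4 by 0.23. The cholesterol call ended without untreated libraries 1 or 2 (camera adjusted p = 0.166 and 0.0569), without asbestos library 3 (0.0864) and after TMM rescaling (0.0806), and the scavenger call without asbestos library 1 or 3 (0.0502 each). After quantile normalization the Nrf2 and scavenger lists had adjusted p = 0.0874 and 0.13. Genes with a mean of at least 5 FPKM gave 0.059 for both the Nrf2 and the cholesterol list, and a fit of only these groups gave 0.0722 for cholesterol and 0.0503 for scavenger receptors.

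Tremolite cleavage fragments raised H2-M2 to 11.6 ± 0.809 FPKM (2.84, SE 0.0797, limma adjusted p = 1.87e-10), Inhba to 19.0 ± 1.34 (2.72), Krt79 to 5.76 ± 0.170 (2.43) and Cfb to 56.7 ± 0.621 (2.30). Tgfbi, a matrix protein induced by TGF-beta, rose from 3.70 ± 0.107 to 17.9 ± 1.14 FPKM (2.01, SE 0.0671, limma adjusted p = 2.82e-10) and the macrophage elastase gene Mmp12 from 21.8 ± 1.77 to 79.4 ± 9.75 (1.82). The matricellular gene Nov fell from 199.8 ± 6.03 to 76.8 ± 0.553 FPKM, by 1.37, and cyclin D1, Ccnd1, from 12.1 ± 0.557 to 4.45 ± 0.407, by 1.27. Il1b reached 22.5 ± 1.93 (0.99), Tnf 14.0 ± 1.37 (0.87), Cxcl2 6.53 ± 0.455 (1.51) and Hmox1 176 ± 6.95 FPKM (1.05).

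DNA replication genes fell in 29 of 35 cases after tremolite fragments (31 adjusted over the list alone) and rose in 0, with Mcm6 (-0.48), Mcm5 (-0.42) and Rrm2 (-0.58) and a list median of -0.31. Matrix (10 of 16 rose, 1 fell), growth factor (6 of 11 rose, 1 fell) and alveolar macrophage genes (21 of 29 rose, 4 fell) were called too, with Spp1 (1.55), Tgm2 (1.34) and Csf2rb (1.00). The camera test gave adjusted p = 3.45e-12, 7.25e-07, 0.000183 and 7.34e-11, and all 4 held with an estimated correlation (adjusted p = 0.0375, 0.0334, 0.0241 and 0.0212). NF-kB genes (13 of 17 rose, 0 fell), cytokines (10 of 16 rose, 1 fell), p53 targets (8 of 22 rose, 0 fell), LXR genes (9 of 16 rose, 3 fell) and neutrophil markers (2 of 3 rose, 0 fell) had camera adjusted p = 1.83e-09, 6.54e-05, 0.000208, 0.00215 and 0.00913. Estimating the correlation gave adjusted p = 0.0517, 0.0519, 0.0519, 0.0519 and 0.0519 instead. Among p53 targets Plk2 rose by 0.81, Phlda3 by 0.58 and Cdkn1a, a cyclin-dependent kinase inhibitor gene, from 71.1 ± 3.31 to 80.5 ± 1.22 FPKM (0.18). Nrf2 (10 of 23 rose, 2 fell), lysosome (16 of 33 rose, 3 fell), ribosomal protein (0 of 36 rose, 21 fell) and glycolysis genes (8 of 23 rose, 1 fell) had camera adjusted p = 0.001, 0.000372, 7.85e-07 and 0.00954. With the correlation estimated, adjusted p = 0.221, 0.282, 0.343 and 0.341 resulted. The glycolysis call ended without fragment library 1 (camera adjusted p = 0.0513). Cholesterol synthesis genes, 1 higher and 7 lower of 24, were not called (camera adjusted p = 0.0736). Higher and lower counts adjusted over the list alone were 11 and 1 for matrix genes, 6 and 2 for growth factors, 22 and 5 for alveolar markers, 9 and 0 for p53 targets, 10 and 3 for LXR, 16 and 4 for lysosome, 0 and 27 for ribosomal proteins and 2 and 7 for cholesterol synthesis.

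**Figure D2:**
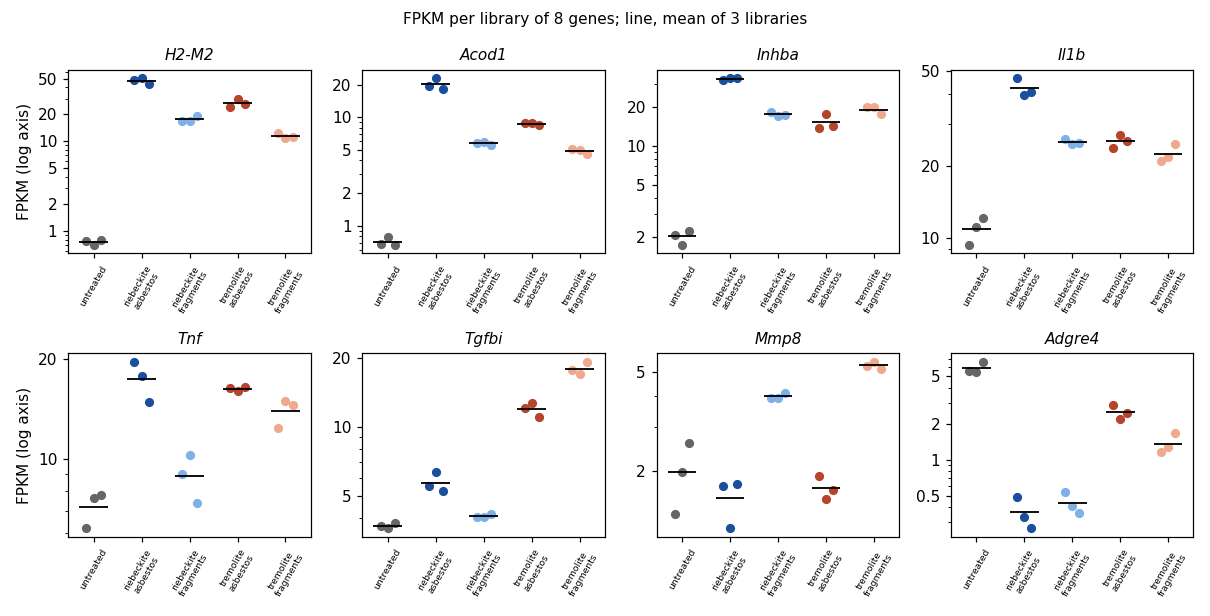
FPKM on a log axis in each of the 15 libraries for 8 genes, with points for libraries, colours for the 5 groups and a line at the mean of 3 libraries. Untreated libraries of H2-M2 average 0.756 FPKM and the treated groups 11.6 to 47.4 FPKM, whereas Adgre4 falls from 5.85 FPKM to between 0.362 and 2.50 FPKM.

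Called in the same direction by all 4 treatments were 1717 genes, 793 higher and 924 lower, of 6013 called in any. This balance depended on the scaling, with 941 higher and 745 lower after TMM rescaling, 849 and 912 after quantile normalization and 679 and 1081 after rescaling to the nuclear genes. H2-M2, Inhba, Cfb, Acod1 and Acp5 rose on average by 3.75, 2.81, 2.74, 2.47 and 2.43 over the 4 treatments, and Adgre4 fell by 1.77. Another 58 genes were higher after some treatments and lower after others. Riebeckite asbestos and fragments shared 1432 higher genes, where independent lists would share 341.9, and 1867 lower genes (593.5), and tremolite asbestos and fragments 916 (132.9) and 1152 (221.6). Both asbestos forms shared 942 (223.3) and 1192 (358.5), and both fragment preparations 1063 (203.4) and 1268 (367). Simulated unchanged groups with shared controls shared at most 0.02 genes on average, but lacked effects and set no bound. Fold changes correlated across genes with r = 0.894 for the riebeckite pair and 0.841 for the tremolite pair, against 0.505 and 0.497 simulated. Their covariances were 0.109 and 0.0563 against 0.00656 and 0.00644 simulated, and for the asbestos forms 0.0714 against 0.00645 and for the fragments 0.0721 against 0.00653. Genes are not independent replicates. The 3 untreated libraries cannot be split into parts of at least a pair, so part of the overlap may come from shared controls. Simulations held only spread between libraries, so an offset of all untreated ones stays in the covariance differences.

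**Figure D3:**
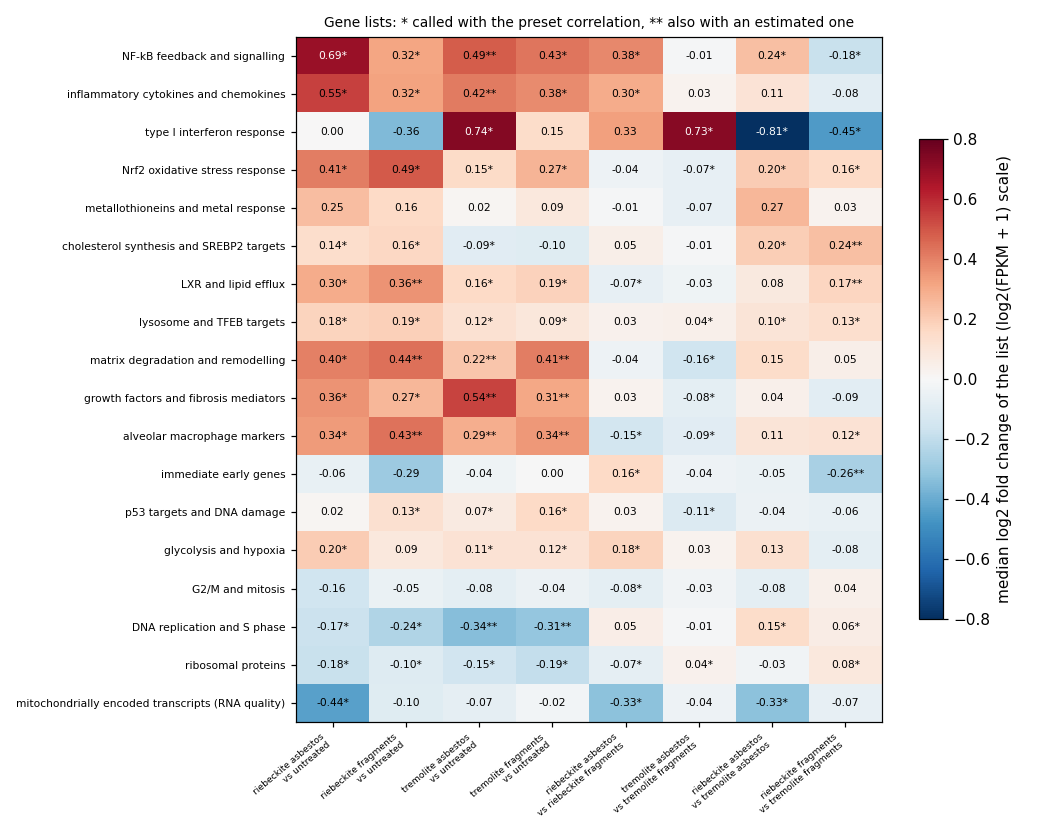
Median log2 fold change on the log2(FPKM + 1) scale for 18 gene lists in 8 comparisons, with 1 asterisk for lists called by camera with the preset correlation and a pair of asterisks for those also called with an estimated correlation. DNA replication lies between -0.17 and -0.34 against untreated cells, and the interferon list is at 0.74 after tremolite asbestos.

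Whether the asbestiform habit matters was asked within each mineral. In riebeckite, asbestos left Acod1 at 20.1 ± 2.58 FPKM against 5.75 ± 0.170 after fragments (1.64, SE 0.0713, limma adjusted p = 1.05e-07), and H2-M2 at 47.4 ± 3.62 against 17.6 ± 1.29 (1.38, SE 0.0797, limma adjusted p = 1.81e-06). Tnf was 17.5 ± 2.40 against 8.89 ± 1.45 (0.90), Inhba 32.6 ± 0.760 against 17.5 ± 0.592 (0.86), Il1b 42.2 ± 3.81 against 25.2 ± 0.694 (0.72) and the bacterial lipoprotein receptor gene Tlr2 115 ± 9.89 against 64.3 ± 2.73 FPKM (0.83). The receptor genes Clec4e and Gpr84 were higher by 0.90 and 0.81. Lower after asbestos were Mmp8 (1.56 ± 0.335 against 4.01 ± 0.0980 FPKM, -0.98), the receptor gene Gpr34 (-0.77) and Cytip (-0.63). Hmox1 was not called (0.15, limma adjusted p = 0.0664).

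NF-kB genes were higher after riebeckite asbestos than after fragments in 13 of 17 cases and lower in 0 (14 and 0 adjusted over the list alone), with Nfkb2 (0.44), Sod2 (0.42) and Icam1 (0.45) and a median of 0.38. Cytokines were higher in 7 of 16 and lower in 1, amino acid response genes in 6 and 0 of 20, glycolysis genes in 9 and 1 of 23, led by Hk2 (0.40), and immediate early genes in 4 and 1 of 16, led by Junb (0.60) and Maff (0.54). These 5 lists had camera adjusted p = 5.45e-11, 0.00233, 0.00813, 0.000711 and 0.0243. An estimated correlation gave adjusted p = 0.149, 0.152, 0.149, 0.285 and 0.149. Mitochondrially encoded transcripts were lower in 12 of 13 cases (median -0.33, or -0.14 after quantile normalization), in the libraries whose mitochondrial share was 6.44% against 7.91%. Alveolar macrophage markers were lower in 13 of 29 and higher in 5, among them Mrc1 (-0.32) and Itgax (-0.26), neutrophil markers lower in 2 of 3, and G2/M genes lower in 5 of 30. Camera gave adjusted p = 1.26e-12, 0.000329, 0.0361 and 0.000315. These became adjusted p = 0.149, 0.149, 0.15 and 0.285 with an estimated correlation. LXR (1 higher, 3 lower of 16), dendritic cell (1 and 2 of 7) and ribosomal protein genes (0 and 2 of 36) had camera adjusted p = 0.0442, 0.0398 and 0.000315. The same lists had adjusted p = 0.232, 0.285 and 0.678 with an estimated correlation. Interferon genes had a median of 0.33 with 0 called higher and 0 lower, and the list was not called (camera adjusted p = 0.221). Its genes stood highest in library 2 of both groups. The higher and lower members adjusted over the list alone numbered 8 and 1 for cytokines, 7 and 1 for amino acid response, 12 and 1 for glycolysis, 8 and 1 for immediate early genes, 5 and 15 for alveolar markers, 0 and 7 for mitosis and 1 and 5 for LXR.

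In the riebeckite pair 712 genes were higher and 409 lower with asbestos, 1121 in all, and libraries did not overlap for 29.0% of genes (10% by chance). The higher share was 63.5% as deposited and 46.0% after TMM rescaling or quantile normalization, so the direction of the balance depended on the scaling. The count was 644 and 730 without asbestos libraries 1 and 2, 665 without fragment library 2, 655 from summed transcripts and 275 with only these groups in the fit. Single libraries ended the LXR call (camera adjusted p = 0.0637, 0.0841 and 0.0624 without asbestos libraries 1, 2 and 3, 0.0937 and 0.0638 without fragment libraries 1 and 3), the dendritic cell call (0.1 and 0.0985 without asbestos library 3 or fragment library 1), the ribosomal call (0.0937 without fragment library 1) and the immediate early call (0.0529 without fragment library 3). After quantile normalization the alveolar, LXR, dendritic cell and neutrophil lists had adjusted p = 0.115, 0.166, 0.0726 and 0.0621. Genes with a mean of at least 5 FPKM gave 0.0532 for LXR, 0.0546 for amino acid response and 0.106 for dendritic cell genes. The dendritic cell call also ended after TMM rescaling (0.063) and without a filter on low values (0.0868), and the neutrophil call with only these groups in the fit (0.0785).

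In tremolite, H2-M2 was again higher after asbestos than after fragments, at 26.6 ± 2.94 against 11.6 ± 0.809 FPKM (1.13, SE 0.0797, limma adjusted p = 3.84e-05), as was Acod1, at 8.69 ± 0.206 against 4.91 ± 0.251 (0.71, SE 0.0713, limma adjusted p = 0.000507). Nov was 103 ± 6.31 against 76.8 ± 0.553 FPKM (0.42). Lower after asbestos were Mmp8 (1.71 ± 0.186 against 5.34 ± 0.183 FPKM, -1.23, SE 0.130, limma adjusted p = 0.00064), the keratin gene Krt79 (2.83 ± 0.382 against 5.76 ± 0.170, -0.82), Tgfbi (11.9 ± 0.896 against 17.9 ± 1.14, -0.55), Srgn (-0.67) and Hmox1 (132 ± 7.44 against 176 ± 6.95, -0.41). Neither Il1b (0.17, limma adjusted p = 0.532) nor Tnf (0.21, limma adjusted p = 0.578) was called.

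The interferon list had a median of 0.73 in tremolite asbestos over fragments (camera adjusted p = 1.34e-13, and adjusted p = 0.373 with an estimated correlation), with 0 of 26 genes called over all genes and 4 higher adjusted over the list alone. Matrix genes were lower in 4 of 16 cases and higher in 1, growth factors lower in 1 of 11, alveolar macrophage markers lower in 5 of 29 and higher in 2, Nrf2 genes lower in 2 of 23 and neutrophil markers lower in 2 of 3. With p adjusted over the list alone, higher and lower counts were 3 and 7 for matrix, 0 and 4 for growth factors, 3 and 11 for alveolar markers, 0 and 6 for Nrf2 genes and 1 and 2 for neutrophil markers. These lists had camera adjusted p = 0.00186, 0.00683, 0.00126, 0.00203 and 0.0105. Estimating the correlation gave adjusted p = 0.152, 0.152, 0.152, 0.327 and 0.152 instead. Called p53 targets and genes of the unfolded protein response numbered 0 and 0, lysosome genes 1 and ribosomal protein genes 0. The p53 list was lower (median -0.11) and the other lists higher with asbestos, with camera adjusted p = 0.00126, 0.0105, 0.0153 and 0.00756. With the correlation estimated, adjusted p = 0.152, 0.327, 0.648 and 0.885 resulted. Higher and lower counts adjusted over the list alone were 1 and 4 for p53 targets, 1 and 0 for unfolded protein response and 2 and 0 for lysosome. NF-kB genes (median -0.0073, camera adjusted p = 0.915), cytokines (0.031, 0.95) and mitochondrially encoded transcripts (-0.041, 0.313) were not called.

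This comparison called 41 genes higher and 59 lower, 100 in all, and libraries did not overlap for 17.0% of genes (10% by chance). The count was 45 and 39 without asbestos libraries 1 and 3, 31, 43 and 61 without fragment libraries 1, 2 and 3, 43 from summed transcripts and 29 with only these groups in the fit. The lysosome and ribosomal calls ended without asbestos library 1 (camera adjusted p = 0.218 and 0.685) or 3 (0.108 and 0.283) or fragment library 2 (0.101 and 0.117), the unfolded protein call without asbestos library 3 (0.163) and the alveolar call without asbestos library 2 (0.0624). The lysosome median of 0.038 was 0.021 and 0.023 without asbestos libraries 1 and 3 and 0.0056 without fragment library 2, the ribosomal median of 0.037 was 0.0032, 0.087 and 0.021 without asbestos libraries 1, 2 and 3, and the unfolded protein median of 0.052 was 0.021 without asbestos library 3. Quantile normalization gave adjusted p = 0.255 for lysosome, 0.41 for ribosomal protein and 0.0647 for unfolded protein response genes. The matrix call ended among genes with a mean of at least 5 FPKM (0.114), where the median of -0.16 became -0.081.

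The minerals were then compared at the same habit. Riebeckite asbestos exceeded tremolite asbestos in Slc6a12, a betaine transporter gene (43.7 ± 5.84 against 14.3 ± 0.984 FPKM, 1.54, SE 0.0823, limma adjusted p = 2.49e-07), Acp5 (35.3 ± 2.04 against 13.3 ± 0.462, 1.35), Csn2 (1.36), the haptoglobin gene Hp (1.36) and Gpr84 (1.19). Il1b (0.71) and Hmox1 (0.61) were higher as well. Ms4a8a was lower (6.05 ± 0.469 against 19.4 ± 2.10 FPKM, -1.53, SE 0.0683, limma adjusted p = 7.54e-08), as were Olfm1 (-1.45), Adgre4 (-1.36) and Emilin2 (-1.32). Cholesterol synthesis genes were higher in 14 of 24 cases and lower in 0 (15 and 0 adjusted over the list alone), with Acat2 (0.79), Mvd (0.38) and Fdps (0.33), Nrf2 genes in 13 and 1 of 23, NF-kB genes in 7 and 0 of 17, and DNA replication genes in 13 and 0 of 35. These 4 lists had camera adjusted p = 2.77e-06, 0.000318, 0.00226 and 0.000443. An estimated correlation gave adjusted p = 0.0754, 0.295, 0.392 and 0.369. The higher and lower members adjusted over the list alone numbered 8 and 0 for NF-kB genes and 15 and 0 for DNA replication.

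Interferon genes were lower with riebeckite than with tremolite asbestos in 9 of 26 cases (16 adjusted over the list alone) and higher in 0, with Mx1 (-1.14) and Irf9 (-0.66) and a median of -0.81, and mitochondrially encoded transcripts were lower in 13 of 13 (median -0.33). The interferon median was -1.23 without riebeckite library 2 and -0.48 without library 3. The mean log2 interferon level was 3.14, 3.78 and 2.43 in riebeckite libraries 1, 2 and 3 and 3.84, 3.92 and 4.28 in those of tremolite, and the mitochondrial share 6.44% against 8.16%. Inflammasome genes were lower in 7 of 14, with Il18 (-0.69) and Txnip (-0.58), and higher in 1. Tested with camera, they had adjusted p = 1.62e-06, 2.33e-08 and 0.0052. These became adjusted p = 0.499, 0.295 and 0.217 with an estimated correlation. Lysosome genes (16 higher, 4 lower of 33) and nuclear respiratory chain genes (7 and 0 of 32) had camera adjusted p = 0.0291 and 0.0466. The same lists had adjusted p = 0.499 and 0.499 with an estimated correlation. With p adjusted over the list alone, higher and lower counts were 19 and 5 for lysosome and 2 and 0 for the respiratory chain. The lysosome call ended without riebeckite library 1 (camera adjusted p = 0.0628) or tremolite library 2 (0.139), and the respiratory chain call without riebeckite library 1 or 3 (0.0833 and 0.0564), without tremolite library 2 (0.307) and after TMM rescaling (0.0718), quantile normalization (0.0846) or a limit to genes with a mean of at least 5 FPKM (0.0782). With only these groups in the fit the lysosome list had 0.0705. In total 1645 genes were higher and 1171 lower with riebeckite asbestos, and libraries did not overlap for 40.6% of genes (10% by chance). The balance was nearly even after TMM rescaling (1435 and 1399), quantile normalization (1433 and 1426) and rescaling to the nuclear genes (1278 and 1266).

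Among fragments, riebeckite exceeded tremolite in Agt, the angiotensinogen gene (14.5 ± 0.845 against 4.77 ± 0.370 FPKM, 1.43, SE 0.0852, limma adjusted p = 7.67e-07), Hpse, heparanase (5.07 ± 0.132 against 1.37 ± 0.0230, 1.36), Acp5 (28.9 ± 1.30 against 12.9 ± 1.87, 1.12) and Tarm1 (1.47). Tgfbi was lower (4.08 ± 0.0733 against 17.9 ± 1.14 FPKM, -1.90, SE 0.0671, limma adjusted p = 8.08e-09), as were Fn1, fibronectin (2.00 ± 0.170 against 6.01 ± 0.372, -1.22), Cxcl2 (2.46 ± 0.380 against 6.53 ± 0.455, -1.13), Olfm1 (-1.42) and the asparagine synthetase gene Asns (-0.79). Cholesterol synthesis genes were higher in 12 of 24 cases and lower in 0 (15 and 0 adjusted over the list alone), with Fdps (0.31), Acat2 (0.40) and Hsd17b7 (0.42), and LXR genes in 7 and 1 of 16 (8 and 1 over the list alone), with Scd1 (0.44) and Abca1 (0.40). Immediate early genes were lower in 8 of 16 and higher in 0, with Klf2 (-0.70), Jun (-0.43) and Myc (-0.39). These 3 lists had camera adjusted p = 1.68e-10, 3.58e-05 and 2.08e-05, and held with an estimated correlation (adjusted p = 0.00945, 0.0247 and 0.0134).

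Lysosome genes were higher with riebeckite than with tremolite fragments in 15 of 33 cases and lower in 2, Nrf2 genes in 7 and 1 of 23, alveolar macrophage markers in 10 and 3 of 29, with Itgax (0.40), DNA replication genes in 4 and 0 of 35, and neutrophil markers in 2 and 0 of 3, with S100a8 (0.85) and Cxcr2 (0.84). The camera test gave adjusted p = 9.13e-06, 2.38e-05, 0.000493, 0.00207 and 0.0234. Estimating the correlation gave adjusted p = 0.185, 0.139, 0.139, 0.329 and 0.139 instead. NF-kB genes were lower in 6 of 17 and higher in 0, with Icam1 (-0.27), and interferon, inflammasome and amino acid response genes lower in 1 of 26, 1 of 14 and 5 of 20. Camera gave adjusted p = 0.000267, 0.00757, 0.0495 and 0.0209. With the correlation estimated, adjusted p = 0.185, 0.698, 0.185 and 0.158 resulted. Riebeckite fragment libraries 1, 2 and 3 had mean log2 interferon levels of 2.47, 3.55 and 2.35, and those of tremolite fragments 3.20, 3.25 and 3.45. Iron handling (3 higher, 0 lower of 13), nuclear respiratory chain (2 and 0 of 32) and ribosomal protein genes (0 and 0 of 36) had camera adjusted p = 0.0246, 0.0128 and 0.000267. An estimated correlation gave adjusted p = 0.185, 0.446 and 0.564. Higher and lower counts adjusted over the list alone were 19 and 3 for lysosome, 12 and 1 for Nrf2 genes, 14 and 6 for alveolar markers, 7 and 0 for DNA replication, 2 and 1 for neutrophil markers and 0 and 9 for NF-kB genes. They were 0 and 0 for interferon, 0 and 3 for inflammasome, 4 and 1 for iron handling and 1 and 0 for respiratory chain.

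Between the fragments 564 genes were higher and 638 lower with riebeckite, 1202 in all, and libraries did not overlap for 3393 of 10616 genes (10% by chance). The balance turned with the scaling, since 656 genes were higher and 511 lower after TMM rescaling and 592 and 584 after quantile normalization, whereas rescaling to the nuclear genes gave 378 and 995. The count was 717 without riebeckite library 1, 782, 717 and 724 without tremolite libraries 1, 2 and 3, 731 from summed transcripts and 676 with only these groups in the fit. Without riebeckite library 1 the interferon, iron, respiratory chain and ribosomal calls ended (camera adjusted p = 0.0791, 0.0798, 0.15 and 0.0604), without library 2 the amino acid (0.0502) and inflammasome calls (0.0634), and without library 3 the interferon (0.319), amino acid (0.0707) and inflammasome calls (0.129), the last also without tremolite library 3 (0.112). After quantile normalization iron, respiratory chain, ribosomal and alveolar macrophage lists had adjusted p = 0.126, 0.126, 0.126 and 0.136, and the inflammasome list 0.0517 after TMM rescaling, 0.0538 with a pseudocount of 0.1 and 0.0547 after rescaling to the nuclear genes. Genes with a mean of at least 5 FPKM gave 0.0609 for inflammasome, 0.114 for iron and 0.127 for amino acid response genes, and a fit of only these groups 0.117 for neutrophil markers.

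Averaged over both minerals, asbestos raised H2-M2 above fragments by 1.25 (limma adjusted p = 7.96e-08) and Acod1 by 1.18 (7.96e-08), and Mmp8 fell by 1.10 (4.11e-05), among 287 genes higher and 283 lower. NF-kB genes were higher in 7 of 17 cases and lower in 0, cytokines in 5 and 1 of 16, glycolysis genes in 3 and 0 of 23 and interferon genes in 0 and 0 of 26 (median 0.48). Camera gave adjusted p = 3.02e-08, 0.0154, 0.000275 and 2.91e-07, and 0.145, 0.263, 0.263 and 0.415 with an estimated correlation. Of these lists, interferon was called only in the tremolite pair and the others only in riebeckite. Alveolar macrophage markers were lower in 12 of 29 cases and higher in 2, mitochondrially encoded transcripts lower in 9 of 13, neutrophil markers in 2 of 3, p53 targets in 3 of 22, Nrf2 genes in 1 of 23 and G2/M genes in 0 of 30. The mitochondrial share was 6.44 and 8.16% after asbestos and 7.91 and 8.42% after fragments of riebeckite and tremolite. Within each riebeckite group interferon genes were highest in library 2. The camera test gave adjusted p = 4.75e-07, 1.39e-10, 0.0112, 0.0108, 0.002 and 0.00078. The same lists had adjusted p = 0.11, 0.228, 0.145, 0.263, 0.263 and 0.326 with an estimated correlation. The amino acid response (3 of 20 higher) and LXR lists (2 of 16 lower) had camera adjusted p = 0.0441 and 0.0473. Estimating the correlation gave adjusted p = 0.263 for both. With p adjusted over the list alone, higher and lower counts were 10 and 0 for NF-kB genes, 8 and 3 for cytokines, 9 and 0 for glycolysis, 4 and 15 for alveolar markers and 0 and 12 for mitochondrial transcripts. They were 1 and 2 for neutrophil markers, 1 and 4 for p53 targets, 0 and 2 for Nrf2 and 1 and 2 for LXR. The amino acid and LXR calls ended without several single libraries, LXR at adjusted p = 0.0665, 0.0629 and 0.0666 without riebeckite asbestos libraries 1, 2 and 3, 0.0872 without riebeckite fragment library 1, 0.139 without tremolite asbestos library 2, and 0.0665 and 0.056 without tremolite fragment libraries 1 and 2. The amino acid list ended at 0.0911 and 0.06 without riebeckite asbestos libraries 1 and 2, 0.09 and 0.0798 without riebeckite fragment libraries 2 and 3, 0.15 without tremolite asbestos library 3 and 0.0561 without tremolite fragment library 1. The LXR call also ended after quantile normalization (0.0538) and with a pseudocount of 0.1 (0.054), and the cytokine and amino acid calls among genes with a mean of at least 5 FPKM (0.0523 and 0.0584). The total of 570 genes became 354 and 378 without tremolite fragment libraries 1 and 3, 285 from summed transcripts, and the higher share of 50.4% became 43.1% after TMM rescaling and 37.7% after quantile normalization.

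The difference between asbestos and fragments was itself compared between minerals. It was larger in riebeckite for Acod1 (log2 1.64 against 0.71, limma adjusted p = 0.00087 for the difference) and Tlr2 (0.83 against 0.056, 0.00087), and Inhba was 0.86 in riebeckite and -0.31 in tremolite (0.000708). Tgfbi (0.40 and -0.55, 0.000708), Hmox1 (0.15 and -0.41, 0.00142), Krt79 (0.053 and -0.82, 0.00087) and Nov (-0.23 and 0.42, 0.000329) differed too. In all, 417 genes differed, 281 with the more positive effect in riebeckite and 136 in tremolite. NF-kB genes did so toward riebeckite in 7 of 17 cases (13 adjusted over the list alone), cytokines in 6 of 16 and amino acid response genes in 3 of 20, and mitochondrially encoded transcripts toward tremolite in 4 of 13. List medians were 0.41, 0.22, 0.18 and -0.28, with camera adjusted p = 1.10e-09, 0.00394, 0.02 and 3.04e-09. With the correlation estimated, adjusted p = 0.21, 0.258, 0.258 and 0.258 resulted. Interferon, ribosomal protein and G2/M genes, with 0, 0 and 1 members called lower, had medians of -0.36, -0.10 and -0.078, camera adjusted p = 0.00154, 1.32e-06 and 0.0122. An estimated correlation gave adjusted p = 0.771, 0.577 and 0.577. The higher and lower members adjusted over the list alone numbered 6 and 0 for amino acid response and 0 and 10 for mitochondrial transcripts. The interferon median rested on single libraries. It was 0.0020 without riebeckite asbestos library 3 and 0.059 without riebeckite fragment library 2, both of the opposite sign, and -0.72, -0.58 and -0.22 without riebeckite asbestos library 2, riebeckite fragment library 3 and tremolite asbestos library 3. The ribosomal median was -0.069 without riebeckite fragment library 1, the mitochondrial median -0.094 after quantile normalization and the cytokine median 0.38 among genes with a mean of at least 5 FPKM. Within each riebeckite group interferon genes were highest in library 2. The mitochondrial share was 6.44 and 7.91% after riebeckite asbestos and fragments and 8.16 and 8.42% after those of tremolite. The higher share of 67.4% became 48.6% after TMM rescaling and 54.5% after quantile normalization. The count was 216 without riebeckite asbestos library 1, 217 without riebeckite fragment library 2, 267 and 214 without tremolite asbestos libraries 1 and 3, 242 and 210 without tremolite fragment libraries 1 and 2, and 197 from summed transcripts. The interferon call ended (camera adjusted p = 0.22 without riebeckite asbestos library 3, 0.353 without riebeckite fragment library 2), as did the G2/M call (0.0545 without tremolite asbestos library 3, 0.0585 without tremolite fragment library 1) and the amino acid call (0.052 without riebeckite fragment library 3, 0.0917 without tremolite asbestos library 2, 0.127 among genes with a mean of at least 5 FPKM).

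Libraries within the riebeckite groups stood apart in interferon genes. The mean log2 level of the 26 interferon genes was 3.14, 3.78 and 2.43 in riebeckite asbestos libraries 1, 2 and 3 and 2.47, 3.55 and 2.35 in riebeckite fragment libraries 1, 2 and 3. It was 3.29, 3.20 and 3.26 in untreated cells, 3.84, 3.92 and 4.28 after tremolite asbestos and 3.20, 3.25 and 3.45 after tremolite fragments. All 26 genes were highest in library 2 of both riebeckite groups. Without these libraries, a choice made after the data were seen, 394 genes differed in the riebeckite pair, and without both libraries numbered 1 or 3 the counts were 439 and 647.

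**Figure D4:**
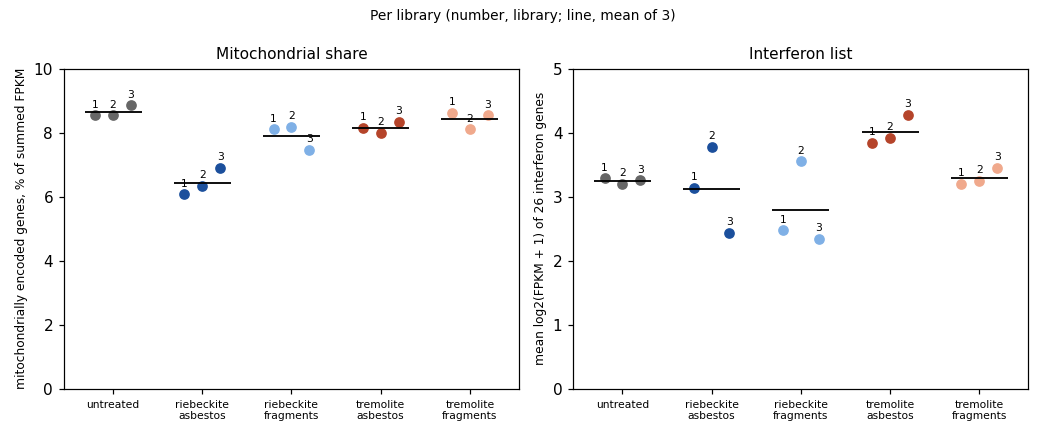
Share of mitochondrially encoded genes in summed FPKM, in %, and mean log2(FPKM + 1) of 26 interferon genes, for each library by its number, with a line at the mean of 3 libraries. The mitochondrial share is lowest after riebeckite asbestos, 6.08 to 6.90%, and the interferon mean is highest in library 2 of both riebeckite groups.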

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

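Chosen only after the result was seen were the exchange of the tremolite labels and the tests that weigh the difference in counts between minerals, the interferon libraries and the mitochondrial transcripts. The difference between asbestos and fragments differed between riebeckite and tremolite in 417 genes by the test of that difference. Among the named genes, its log2 size (riebeckite minus tremolite) was 1.17 for Inhba, 1.10 for Slco4a1, 1.03 for Cxcl2, 1.00 for Gpr84, 0.95 for Tgfbi, 0.93 for Acod1, 0.88 for Krt79, 0.77 for Tlr2, 0.77 for Gdf15, 0.69 for Tnf, 0.60 for Procr, 0.57 for Hmox1 and 0.55 for Il1b. It was -0.58 for Cytip, -0.64 for Adgre4, -0.65 for Nov, -0.68 for Ccnd1 and -0.94 for Slc8b1. List medians were 0.41 for NF-kB genes, 0.22 for cytokines, 0.18 for amino acid response genes, -0.28 for mitochondrially encoded transcripts, -0.10 for ribosomal proteins (-0.069 without riebeckite fragment library 1) and -0.078 for G2/M genes. The interferon median of -0.36 rested on single libraries, at 0.0020 without riebeckite asbestos library 3 and 0.059 without riebeckite fragment library 2 (camera adjusted p = 0.22 and 0.353), and -0.72, -0.58 and -0.22 without riebeckite asbestos library 2, riebeckite fragment library 3 and tremolite asbestos library 3. The mitochondrial median was -0.094 after quantile normalization. Sums of transcripts gave limma adjusted p = 0.489 for Slco4a1, 0.266 for Procr, 0.0801 for Tnf, 0.0593 for Gdf15, 0.0566 for Adgre4 and 0.0546 for Il1b.

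Calls of 5 of these genes lay near the threshold, at limma adjusted p = 0.0392 for Tnf, 0.0337 for Slc8b1, 0.0276 for Il1b, 0.0348 for Gdf15 and 0.0274 for Adgre4, and ended when many of the 12 treated libraries were left out in turn, with fewer libraries in each fit and folds of similar size. The adjusted p for Tnf passed 0.05 without riebeckite asbestos libraries 1 and 2 (0.0906 and 0.0793), riebeckite fragment libraries 1 and 3 (0.0645 and 0.0682), tremolite asbestos libraries 1, 2 and 3 (0.0752, 0.0655 and 0.0785) and tremolite fragment libraries 2 and 3 (0.101 and 0.0812), with log2 sizes of 0.58 to 0.71. For Slc8b1 it did so without riebeckite asbestos libraries 1, 2 and 3 (0.0578, 0.0745 and 0.0615), riebeckite fragment libraries 1 and 3 (0.0728 and 0.065), tremolite asbestos libraries 2 and 3 (0.065 and 0.0841) and tremolite fragment libraries 1, 2 and 3 (0.0751, 0.06 and 0.0671), with sizes of -0.997 to -0.829. The Il1b call ended without riebeckite asbestos library 1 (0.0671), riebeckite fragment libraries 2 and 3 (0.0648 and 0.0528), tremolite asbestos libraries 1 and 3 (0.0669 and 0.0623) and tremolite fragment libraries 2 and 3 (0.0558 and 0.0616), with sizes of 0.48 to 0.57. That of Gdf15 ended without riebeckite asbestos libraries 1 and 3 (0.0853 and 0.0575), riebeckite fragment libraries 2 and 3 (0.086 and 0.0707), tremolite asbestos libraries 1 and 2 (0.0772 and 0.0579) and tremolite fragment libraries 2 and 3 (0.088 and 0.0705), with sizes of 0.67 to 0.78, and that of Adgre4 without riebeckite asbestos libraries 2 and 3 (0.0566 and 0.0577), riebeckite fragment libraries 1 and 2 (0.0607 and 0.0571), tremolite asbestos libraries 1 and 3 (0.0648 and 0.0585) and tremolite fragment libraries 1 and 2 (0.0674 and 0.0693), with sizes of -0.65 to -0.57. The Tnf call also ended after TMM rescaling (0.0513), after quantile normalization (0.0526) and with only the groups compared in the fit (0.0515), as did that of Gdf15 in the last case (0.0677).

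Of 100 splits of the treated libraries, the real one alone reached 417 genes for the difference between minerals (highest other 339). Exchanging only the tremolite labels, not among the 100, gave the mean asbestos effect and 570 genes. The splits assume no asbestos effect, so they cannot test if it differs. For that mean effect 1 of 100, the real one, reached 570 (highest other 369). For any group difference 1 reached 5060 (highest other 3). Both argue against chance only if the cultures were separate. For 3 against 3 libraries, 10 splits are too few for a share under 0.05. The real and highest other counts were 4807 and 1 for riebeckite asbestos against untreated cells, 4073 and 1 for riebeckite fragments, 2540 and 1 for tremolite asbestos and 2920 and 1 for tremolite fragments. They were 1121 and 60 for the riebeckite pair, 100 and 4 for the tremolite pair, 2816 and 1 between the asbestos forms and 1202 and 1 between the fragments.

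Asbestos and fragments differed in 1121 genes in riebeckite and 100 in tremolite. Without both riebeckite libraries numbered 2 the counts were 394 and 125, and under TMM and quantile scaling the riebeckite count was 1062 each time against 97 and 112, which argues against these libraries or the scaling as the whole source. The tremolite count was 45 and 39 without asbestos libraries 1 and 3, and 31, 43 and 61 without fragment libraries 1, 2 and 3, and the riebeckite count 644 and 730 without asbestos libraries 1 and 2 and 665 without fragment library 2. The mineral, the particle dimensions and the unequal mass doses (9 and 40 µg/cm² against 5 and 60) stay open and were not tested.

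In both riebeckite groups all 26 interferon genes were highest in library 2. Number 2 had the highest mean in 2 of 5 groups, which argues against a batch marked by this number across all groups. An exchange with tremolite asbestos RNA would place other genes near 1 on a scale from the group's remaining libraries (0) to tremolite asbestos (1), and the median positions were 0.157 (quartiles -0.0212 and 0.374, 2462 genes) for asbestos and 0.174 (-0.00498 and 0.432, 1461 genes) for fragments, against 0.809 and 0.724 for the interferon list. That argues against an exchange or a mixture of more than a small share. A batch shared by the riebeckite libraries alone remains a candidate explanation, and no biological explanation was tested.

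Mitochondrially encoded transcripts fell after riebeckite asbestos with a median of -0.44 (13 genes, quartiles -0.46 and -0.36). The median of 10603 nuclear genes was -0.0166 (quartiles -0.177 and 0.156), where dilution by a few transcripts would lower it too. That of the 32 nuclear respiratory chain genes was 0.0686 (quartiles -0.0416 and 0.156), which argues against a joint fall of both genomes' respiratory genes. More total nuclear mRNA, hidden by FPKM, less mitochondrial RNA per cell, RNA quality and oligo(dT) yield stay open, since no value separates them.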

How the results depend on the processing

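The omissions of both riebeckite libraries with the same number and the rescaling to nuclear genes were chosen after the data were seen. Counts stayed within 1.5 times under TMM rescaling, quantile normalization, a pseudocount of 0.1, either filter on low values, no mean-variance trend and rescaling to nuclear genes. With only the groups compared in the fit, which leaves fewer libraries to estimate the spread, 275 genes were called in the riebeckite pair, 29 in the tremolite pair and 676 between the fragments. From summed transcripts the counts were 655, 43 and 731, with 197 for the difference between minerals and 285 for the mean asbestos effect, and the cause was not tested. An absolute log2 fold change of at least 1, a stricter threshold by construction, left 256, 189, 67 and 92 genes against untreated cells (riebeckite asbestos, riebeckite fragments, tremolite asbestos, tremolite fragments), 4 and 3 in the riebeckite and tremolite pairs, 51 between the asbestos forms, 19 between the fragments, 4 for the difference between minerals, 4 for the mean effect and 50 shared by all treatments. Without both riebeckite libraries numbered 2 the riebeckite pair had 394 genes, the difference between minerals 192 and the mean effect 278. Without those numbered 1 these were 439, 161 and 304, with 745 between the fragments, and without those numbered 3 the riebeckite pair had 647. Fewer libraries entered these fits.

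Leaving out each library gave 4117 to 4452, 3418 to 3809, 2013 to 2299 and 2371 to 2547 genes against untreated cells in the order above, 644 to 878 in the riebeckite pair, 31 to 92 in the tremolite pair, 2065 to 2547 between the asbestos forms and 717 to 970 between the fragments. The difference between minerals ranged from 210 to 425, the mean effect from 354 to 547, any difference from 4385 to 5037 and the genes shared by all treatments from 1418 to 1696. Over the 8 comparisons of a pair of groups camera called 100 lists. Of these calls, 17 were kept in the same direction with an estimated correlation, 90 by fry, 95 after TMM rescaling, 86 after quantile normalization, 99 after rescaling to the nuclear genes, 99 with a pseudocount of 0.1 or no filter, 83 among genes with a mean of at least 5 FPKM, 95 with only the groups compared in the fit, 91, 95 and 89 without both riebeckite libraries numbered 1, 2 and 3, and 92 to 100 with a library left out. The totals called were 17 with an estimated correlation, 150 by fry and 92 to 103 with a library left out.

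Over all comparisons, tests of named genes lost their call 25 times and gained one 15 times after TMM rescaling, 35 and 20 times after quantile normalization, 8 and 6 times with a pseudocount of 0.1, and 123 and 13 times with only the groups compared in the fit. Sums of transcripts ended 109 calls and added 1. With each library left out in turn, 631 tests lost their call, 72 gained one and 8531 stayed on the same side of the threshold. Among named genes the direction turned in 11 cases, and the cause was not tested. After quantile normalization Marco was at -0.14 (limma adjusted p = 0.00851) after riebeckite asbestos and -0.091 (0.0816) after riebeckite fragments, Itgb2 at 0.045 (0.205) in the riebeckite pair and Spp1 at 0.21 (0.0232) for the difference between minerals. From summed transcripts Mdm2 was at -0.23, -0.33, -0.43 and -0.34 against untreated cells (limma adjusted p = 0.696, 0.584, 0.541 and 0.625), Slc11a1 at -0.23 (0.845) in the riebeckite pair, and Gbp9 at 0.22 (0.606) and Rps6 at 0.018 (0.935) between the asbestos forms.

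The labels give the replicate number no meaning beyond a name, and deviations of libraries with the same number correlated at -0.0126 to 0.106, -0.0494 to 0.172 and -0.0613 to 0.101 for numbers 1 to 3, not above the 0.1 required in every pair, so the numbers were not used to pair libraries. By mean correlation, 8 of 15 libraries were closest to those with their own number, against 5 on average over all 1296 renumberings within groups, of which 248 gave as many (exact permutation p = 0.191). This leaves a partial link open, as for library 2 of both riebeckite groups, where all 26 interferon genes were highest. With the replicate number as a block, 4893, 4147, 2649 and 3006 genes were called against untreated cells, 1191 and 99 in the riebeckite and tremolite pairs, 2931 between the asbestos forms, 1315 between the fragments, 416 for the difference between minerals and 635 for the mean effect. Tests on counts were not run, since FPKM hold no counts. The depth is unknown, so its effect on low genes could not be assessed.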

Other observations

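The tests of gene families and of lists called in opposite directions were chosen after the data were seen. Among 263 families of genes with a common symbol stem, tested in 8 comparisons, the Kruppel-like transcription factors were lower with riebeckite than with tremolite. Between the asbestos forms 8 of 11 were lower and 1 higher (median -0.27, camera adjusted p = 0.0139, and adjusted p = 0.989 with an estimated correlation), and between the fragments 7 were lower and 0 higher (-0.18, 0.0111, and 0.889 with an estimated correlation). Nop genes of ribosome assembly were lower in 5 of 8 cases after tremolite asbestos (-0.25, 0.00747, and 0.497 with an estimated correlation) and 6 of 8 after tremolite fragments (-0.27, 0.00562, and 0.455 with an estimated correlation). Genes named for CD surface antigens, which share a naming scheme rather than descent, were lower with asbestos in the riebeckite pair in 14 of 54 cases and higher in 2 (-0.10, camera adjusted p = 0.000369), and this call held (adjusted p = 0.046 with an estimated correlation). These directions were the same under TMM, quantile and nuclear scaling, and the families were not tested with single libraries left out.

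A hypothesis was that all treatments evoke 1 shared response of different strength. Correlations of effects were corrected for simulated noise with shared controls. They were 0.941 for riebeckite asbestos and fragments, 0.925 for the tremolite pair and 0.869 for both fragments. Riebeckite asbestos had 0.851 and 0.834 with tremolite fragments and asbestos, and riebeckite fragments 0.794 with tremolite asbestos. The lowest lay between the bounds of 0.9 and 0.7 set for and against the hypothesis, so it stays undecided. Of the gene lists, 1 was called in opposite directions, cholesterol synthesis, with medians of 0.14 and 0.16 after riebeckite asbestos and fragments and -0.09 after tremolite asbestos (camera adjusted p = 0.0136, 0.0106 and 0.0495). With an estimated correlation the adjusted p = 0.193, 0.146 and 0.239, and the tremolite call ended after TMM rescaling (0.0806) and without untreated library 1 (0.166), untreated library 2 (0.0569) or tremolite asbestos library 3 (0.0864), so this list does not settle it. Its tremolite median was -0.052 after TMM rescaling and -0.049 without untreated library 1, and its riebeckite medians were 0.09 and 0.11 after rescaling to the nuclear genes.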
